A study of Rattus norvegicus with 4 samples.

How the data were processed

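Total RNA from cultured embryonic rat cortical neurons was extracted with Trizol, turned into sense-strand target with a whole-transcript expression kit, labelled with biotin and hybridised to 1-colour Affymetrix whole-transcript arrays, per the labels' protocols. The 4 arrays form 2 groups of 2, infected with lentivirus carrying control shRNA or PHF6 shRNA, and the grouping was taken from the sample titles. The design text states that PHF6 knockdown was checked by quantitative PCR before the arrays were run. Those PCR values were not used here.

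The deposited values are probe set intensities made by the authors with RMA, per the submitters' processing notes. RMA corrects background, normalizes probes between arrays by quantiles and summarises each probe set. The version and settings are not given in the sources used here. RMA normally ends on a log2 scale, but the deposited intensities run from 8.57 to 6121 on a linear scale, so log2 was taken before every test. RMA compresses the differences of dim probe sets, so their fold changes are understated. No scanner files or detection calls were used here, and the number of arrays limits the precision.

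Of 29214 rows, 18644 carry 1 gene symbol in the platform annotation, 962 carry several and 9608 carry none there. Only rows with 1 symbol were named, which gave 17245 genes. Symbols were matched through the gene identifier to the RefSeq annotation of the GRCr8 assembly for 18460 rows and kept as annotated for 184. For the 879 genes with several probe sets, the one with the highest mean over the 4 arrays was used. Some rows may have been left out of the annotation used here, and list members without a row were not analysed: 546 of 619 list genes were measured. A background level was set on each array at the 95th percentile of 206 olfactory and vomeronasal receptor genes.

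Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, default prior, no filter, no covariate) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 3.46 degrees of freedom. Differences are PHF6 shRNA minus control shRNA in log2 units, given with limma's SE. Gene lists were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over 26 lists. The lists covered PHF6 partner complexes, migration, guidance, synapse, receptor and channel genes, markers of neurons, glia and other cells, and stress, growth and metabolic responses. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule named Phf6 and Cspg5, then, among genes past the threshold with non-overlapping arrays, the 12 highest and 12 lowest differences. Where too few passed, as here, places were filled by the largest differences among genes with an unadjusted p under 0.01 and non-overlapping arrays, leaving out symbols starting with LOC, RGD and a digit, Olr, Vom or Mir. Up to 4 members of each list were named by smallest p, and others in the list paragraphs were added after their values were seen.

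On simulated data with the real means, 17245 genes, the fitted variances and 100 genes changed at each fold size in each of 10 runs, the fit without a block recovered on average 82.8% of 2-fold and 98.8% of 4-fold changes, with 9.3 false calls. These simulated arrays held no difference shared by same-numbered arrays. With such a difference added, the same fit recovered 77.6% and 98.7%, with 0.1 false calls. The changed genes were drawn from those above background on all 4 arrays, so these shares may not hold for dim genes or for fewer changed genes. In the real arrays 29 genes differed at least 2-fold without overlap between the groups, and none passed. In 20 simulated runs with 1 list shifted by 0.3 log2 units, camera recovered the list in 20 and called no other. Genes varied independently in these runs, while the estimated correlation within the real lists reached 0.72. The runs therefore cannot show how often camera falsely calls lists of correlated genes. The shift was larger than any list median found here, and the immediate early list was not among those shifted. Alternatives were a fit with the duplicate number as a block, leaving out each array in turn, 3 other scalings (a further quantile normalization, centring on the median, cyclic loess), 2 filters on dim genes, other eBayes priors, array weights, the mean of a gene's probe sets, all rows, an adjusted p under 0.10, and limma's treat against a 1.2-fold change. No arrays of the series were left out of the main comparison, and no pair of arrays shared more than 11 identical values.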

Results

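Gene expression was profiled on 4 arrays of total RNA from cultured rat cortical neurons. The neurons came from Sprague Dawley embryos at embryonic day 18 and had been infected with pLL3.7 lentivirus, a vector that delivers a short hairpin RNA (shRNA) into cells that do not divide. In 2 arrays the virus carried a control shRNA and in 2 arrays it carried an shRNA against PHF6, a nuclear protein with PHD-type zinc fingers whose gene lies on the X chromosome and is mutated in a form of intellectual disability. RNA was collected 5 days after infection. The comparison addresses which transcripts differ in cortical neurons that carry the PHF6 shRNA. Both PHF6 titles name the same shRNA, PHF6shRNA-2, so an effect of PHF6 loss cannot be told apart from other effects of that shRNA. Each array gave 29214 probe set intensities, with medians between 40.9 and 41.7. The 95th percentile of 206 olfactory and vomeronasal receptor genes, which served as a background level, lay between 32.5 and 41.1 intensity units, and 9743 to 11143 of the 17245 named genes exceeded it on an array. This level was 41.1 (control) and 39.9 (PHF6 shRNA) in the duplicates numbered 1, and 32.5 and 32.7 in those numbered 2. The arrays are called biological duplicates in their labels, which do not say whether they came from separate cultures or animals, so the tests measure the spread between these arrays. With 2 arrays per group, an exact test of a single value cannot give a two-sided p below 0.333, and limma's moderated test with Benjamini-Hochberg adjustment over the 17245 genes was used.

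Phf6, the targeted gene, read near background in both groups. Its single named probe set read 5.07 ± 0.05 log2 units in the control arrays and 5.03 ± 0.10 in the PHF6 shRNA arrays (SD, n = 2 each), a difference of -0.03 ± 0.09 (SE) with a limma adjusted p of 0.98. The 4 arrays gave intensities of 32.8 and 34.3 for control and 34.4 and 31.3 for PHF6 shRNA, and only 1 of the 4 exceeded the background level of its array. A signal at background cannot show a knockdown, so this probe set does not check the group labels, and every direction given here rests on those labels. The 95% interval of the difference ran from -0.26 to 0.20.

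Cspg5, which encodes a neural transmembrane chondroitin sulfate proteoglycan also called neuroglycan C, was lower in both PHF6 shRNA arrays than in both control arrays. Its intensities were 249 and 314 in the control arrays and 131 and 184 in the PHF6 shRNA arrays, a difference of -0.85 ± 0.20 log2 units, or 1.80-fold. It did not pass the adjusted threshold in the fit without a block (limma adjusted p = 0.26, unadjusted 0.0061). With the duplicate number as a block it passed (limma adjusted p = 0.0057), but no label states that the numbers pair the arrays. Without the block, leaving out each array in turn gave differences from -1.09 to -0.61 log2 units. The study is known to have picked this gene on these samples, so the value is not independent evidence of its direction.

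By the fixed rule, 12 genes were named for higher signal in the PHF6 shRNA arrays. Syt10, a synaptotagmin that acts in calcium-dependent exocytosis, was at 7.10 ± 0.45 log2 units against 5.02 ± 0.09 in the control arrays, where it was at or near the background level, so its fold is not exact. Rab9b, a small GTPase of the late endosome, was 2.72-fold higher, with intensities of 965 and 1085 against 344 and 412. Calb1, the calcium-buffering protein calbindin, was 2.69-fold higher, with an SD of 0.74 log2 units between the control arrays. Dynlt3, a dynein light chain, was 2.54-fold higher and Myof, a ferlin of membrane repair, 2.46-fold higher. Idi1, an isomerase of isoprenoid and sterol synthesis, was 2.38-fold higher, and Acvr1c, an activin receptor kinase, 2.36-fold higher, with control duplicate 1 below the background level. Prkx, a cAMP-dependent protein kinase, was 2.30-fold higher. Kcna1, the potassium channel Kv1.1, was 2.17-fold higher. Opn3, an opsin, Olfm3, an olfactomedin, and Pcgf3, a Polycomb-group RING finger protein, were 2.49-fold, 2.35-fold and 2.25-fold higher.

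By the same rule, 12 genes were named for lower signal in the PHF6 shRNA arrays. Nsg1, a neuronal endosomal protein that acts in receptor recycling, was 2.11-fold lower, at 8.81 ± 0.25 log2 units against 9.89 ± 0.03. Dnm3, a dynamin, was 2.13-fold lower in its brighter probe set, while a second, dimmer one differed by 0.06. Elavl3, the neuronal RNA-binding protein HuC, was 1.90-fold lower and Ywhag, the gamma form of 14-3-3, 1.84-fold lower, at 9.40 ± 0.17 against 10.28 ± 0.03. Sec11c, a subunit of the signal peptidase complex, was 2.39-fold lower and Fut8, which adds core fucose to N-glycans, 2.02-fold lower. Far2, a fatty acyl-CoA reductase, was 2.04-fold lower. Hivep1, a zinc-finger transcription factor, differed by -1.01 ± 0.10 log2 units, with 8.16 and 8.15 in the control arrays. Nt5dc3, Ccdc6, Nipsnap3b and the kinase gene Stk32b were 2.37-fold, 2.27-fold, 2.26-fold and 2.22-fold lower.

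**Figure D1:**
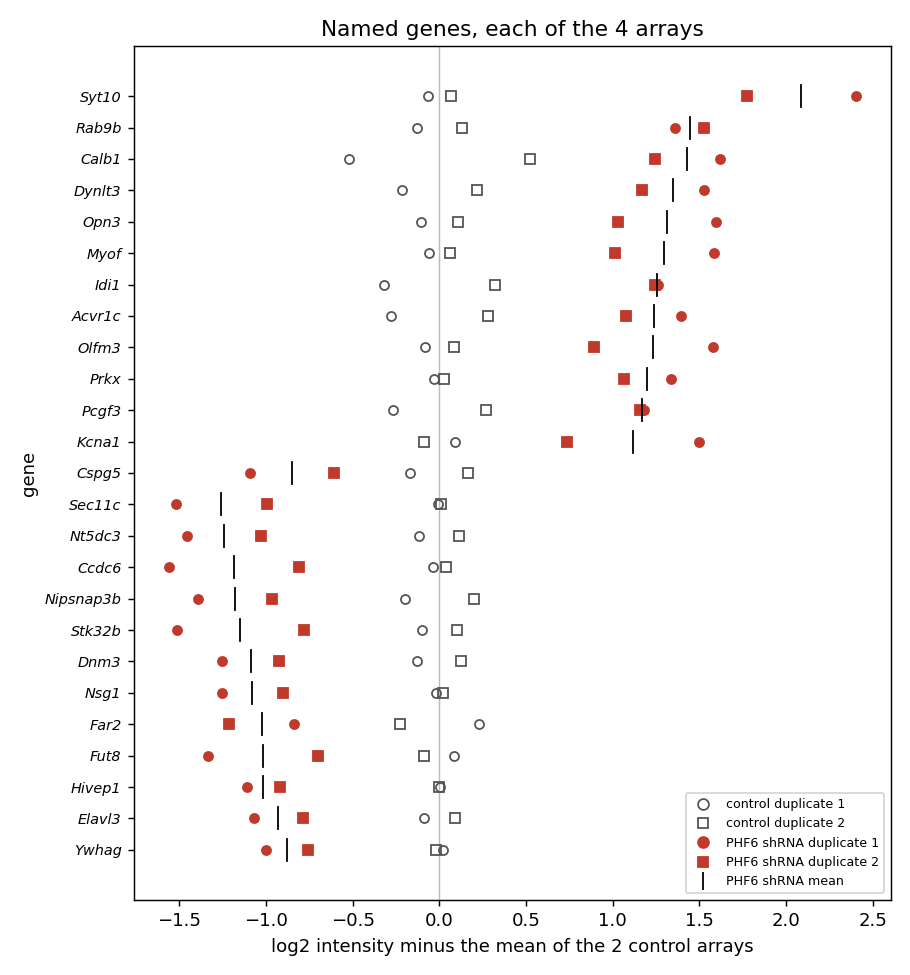
Log2 intensity of Cspg5 and of the 24 genes named by a fixed rule, on each of the 4 arrays, less the mean of the 2 control arrays of that gene; open symbols are control arrays, filled symbols PHF6 shRNA arrays, and the black tick is the PHF6 shRNA mean. For each gene the filled symbols lie on one side of the open ones, which the rule required of the 24 genes, down to a mean of -1.26 for Sec11c, and the control arrays of Syt10, the top gene, are at or near background.

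In the fit without a replicate block, none of these 24 genes passed the adjusted threshold, and neither did any other of the 17245 genes (limma, smallest adjusted p = 0.23). The adjusted p of the 24 genes in this fit ran from 0.23 to 0.28 and their unadjusted p from 4.4e-05 to 0.0076. With the duplicate number as a block 909 genes passed, among them all 24. No label states that the numbers pair the arrays, though the descriptions repeat them after the letters exp, and the question stays open. In the block fit 684 genes also differed by number (limma adjusted p under 0.05). If the numbers pair the arrays, the fit without the block counts this difference as spread between arrays. On simulated data the block fit made 31.6 false calls among 231.6 on average. At an unadjusted p under 0.05, 5% would pass by chance if the arrays varied independently. The fit without the block gave 1862 genes at that level, 10.8% of those tested. Of these, 1297 (69.7%) were lower and 565 higher in the PHF6 shRNA arrays, but cyclic loess scaling gave 53.5% lower and a further quantile normalization 58.0%. At least 1.5-fold with no overlap between the groups' arrays were 122 genes higher and 119 lower, and at least 2-fold 19 higher and 10 lower. The 2 groups did not overlap in 37.8% of all genes, where chance gives 33.3% if the arrays varied independently. The count of genes past the threshold changed when an array was left out. Such fits leave unequal duplicate numbers in the groups, so differences between duplicates enter them. The share lower at an unadjusted p under 0.05 was 79.0% without control duplicate 1, 51.5% without control duplicate 2, 57.5% without PHF6 shRNA duplicate 1 and 66.2% without PHF6 shRNA duplicate 2.

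Of 26 gene lists fixed before the data were examined, 3 passed camera with its preset correlation, 2 toward higher and 1 toward lower signal in the PHF6 shRNA arrays. With an estimated correlation none passed (smallest adjusted p = 0.75), and none passed fry's directional test (smallest adjusted p = 0.46). Camera with an estimated correlation rests on the few residual degrees of freedom of 4 arrays, so it could hardly pass here. The unfolded protein list had an estimated correlation of -0.011, below the preset 0.01, yet its unadjusted camera p rose from 0.010 to 0.11. Values with an estimated correlation therefore say little for or against a list. Members of the lists that passed 0.05 adjusted over the list alone numbered 20, in 10 lists, and none of them passed over all genes tested. List calls changed when an array was left out. The groups then no longer held the same duplicate numbers, so differences between duplicates entered the group difference. The medians of 14 lists changed sign when at least 1 of the arrays was left out. Median, mean and test differed in sign for 3 lists, axon guidance, oligodendrocyte and interferon genes.

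Presynaptic genes were lower as a set. Of 25 measured, 18 were lower, with a median of -0.09 log2 units, or -0.02 under cyclic loess (camera adjusted p = 0.049, adjusted p = 0.75 with an estimated correlation). The brightest 25% of all genes had a median of -0.08, close to that of the list, and 52.3% of all genes were lower. A shift of bright genes in general was therefore not told apart from one of this list. The call held with the duplicate number as a block (camera adjusted p = 0.030). Slc17a6, the vesicular glutamate transporter VGLUT2, differed by -0.69 ± 0.11, Vamp1, a vesicle SNARE, by -0.42 ± 0.08, and the plasma membrane SNARE Stx1a by -0.47 ± 0.10, and these 3 passed adjusted over the list alone. Nrxn3, a presynaptic adhesion molecule, differed by -0.38 ± 0.10 and did not pass. Syn2, a synapsin, went the other way, at 0.33 ± 0.10, and did not pass either. Cplx1, a complexin, differed by -0.35, Syt1 by -0.10 and Snap25 by -0.05. The call was lost without control duplicate 2 (adjusted p = 0.082), without PHF6 shRNA duplicate 2 (0.18), under each of the 3 other scalings, with either filter on dim genes and with array weights. Over 15 alternatives the adjusted p ran from 0.0011 to 0.22.

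GABAergic interneuron markers were higher as a set, 15 of 18, with a median of 0.11 log2 units (camera adjusted p = 0.049, adjusted p = 0.75 with an estimated correlation). Only 14 of the 18 were above background on at least 2 arrays. Dlx1, Vip, Calb2 and Pvalb, all counted as higher, were above it on no array. The list was led by Calb1, which excitatory neurons can also express, and the Dlx transcription factor genes Dlx2, Dlx5 and Dlx6 stood at 0.20, 0.33 and 0.25. Dlx5 was below background on both control arrays, so its difference is not exact. Erbb4, a neuregulin receptor, went the other way, at -0.38. The genes of GABA synthesis differed by 0.16 (Gad1) and -0.02 (Gad2), the vesicular GABA transporter gene Slc32a1 by 0.01 and Sst by 0.16. None of its genes passed adjusted over the list alone. The list passed with the duplicate number as a block (camera adjusted p = 0.017). The median was 0.02 without control duplicate 2 and 0.03 without PHF6 shRNA duplicate 1, against 0.17 and 0.20 without the other 2 arrays. The call was lost without control duplicate 2 (adjusted p = 0.50), without PHF6 shRNA duplicate 1 (0.22), after centring on the median, with either filter on dim genes and with array weights. Over 15 alternatives the adjusted p ran from 0.0026 to 0.50.

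Immediate early genes, which neuronal activity induces, were higher as a set in 12 of 18, with a median of 0.10 log2 units (camera adjusted p = 0.048, adjusted p = 0.75 with an estimated correlation). Nr4a2 and Egr1, 2 transcription factor genes, were higher by 0.50 ± 0.09 and 0.44 ± 0.09 and passed adjusted over the list alone. Egr3, Nr4a3 and Jun differed by 0.36, 0.35 and 0.38. The activity-regulated Npas4, Nr4a1 and Fos had values in the other direction, -0.63 ± 0.61, -0.54 ± 0.28 and -0.28 ± 0.18. The median was -0.0019 without control duplicate 2 and 0.01 without PHF6 shRNA duplicate 1, against 0.18 and 0.27 without the other 2 arrays. The call was lost under 4 of 15 alternatives. These were without control duplicate 2, without PHF6 shRNA duplicate 1, without the dimmest 25% of genes and with the duplicate number as a block (camera adjusted p = 0.057). Under that block 4 members passed toward higher signal and 2, Npas4 and Nr4a1, toward lower signal. Over the alternatives the adjusted p ran from 9.0e-05 to 0.77.

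Protein partners of PHF6 were examined through the PAF1 complex, which acts in transcription elongation, and the NuRD chromatin remodelling complex. Ctr9, a subunit of the PAF1 complex, differed by -0.69 ± 0.16 log2 units and passed adjusted over the list alone (0.033). The other 5 PAF1 genes lay between -0.13 (Rtf1) and 0.05 (Leo1), and the list did not pass (camera adjusted p = 0.30). Of 13 NuRD genes 8 were lower, with a median of -0.14, led by Gatad2b at -0.47 ± 0.13 and Chd5 at -0.32 ± 0.09, and the list did not pass (0.21). It passed toward lower signal without control duplicate 1 and without PHF6 shRNA duplicate 2, and its median was 0.02 without PHF6 shRNA duplicate 1.

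Neuronal migration genes were lower in 23 of 32, with a median of -0.09 log2 units, and did not pass (camera adjusted p = 0.070), though they did under 3 of 15 alternatives, without control duplicate 1, without PHF6 shRNA duplicate 2 and with all rows. Nrp1, a semaphorin receptor, differed by -0.50 ± 0.11, the kinase gene Cdk5 by -0.35 ± 0.09 and Robo1 by 0.28 ± 0.10. Axon guidance genes went both ways, 21 lower and 18 higher of 39, with a median of -0.03 and a mean of 0.01 (camera adjusted p = 0.93). In this list 5 genes passed adjusted over the list alone. The ephrin receptor genes Ephb1 and Epha3 differed by -0.81 ± 0.13 and -0.43 ± 0.08, Sema3e by -0.39 ± 0.08 and Nrp1 as above, and the netrin receptor gene Unc5a by 0.40 ± 0.09. Proteoglycan and matrix genes did not pass (0.21), except without control duplicate 2 and without PHF6 shRNA duplicate 1, and Gpc4, a glypican, differed by 0.50 ± 0.10 and Vcan, versican, by 0.40 ± 0.13. The X-linked intellectual disability genes other than Phf6 were lower in 17 of 27 and did not pass (0.23), except without control duplicate 1, with Cask at -0.33 ± 0.09.

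Receptors and channels contained single members that passed adjusted over the list alone, while none of these lists passed as a set. Among glutamate receptor and postsynaptic genes (16 higher and 16 lower, camera adjusted p = 0.65), the metabotropic receptor gene Grm7 differed by -0.55 ± 0.09 and the kainate receptor gene Grik1 by -0.53 ± 0.09, while Camk2a differed by 0.57 ± 0.16 and did not pass. Among GABA and glycine receptors (0.25), the glycine receptor gene Glra2 differed by -0.68 ± 0.09. Among voltage-gated channels (0.65), Kcnq3 differed by -0.68 ± 0.11, the sodium channel gene Scn3a by -0.81 ± 0.18 and Kcna1 by 1.12 ± 0.25. Fry's test for change in either direction passed for 4 lists, with adjusted p of 0.013 for presynaptic genes, 0.019 for axon guidance, 0.019 for glutamate receptors and 0.049 for the X-linked genes. It does not compare a list with other genes.

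**Figure D2:**
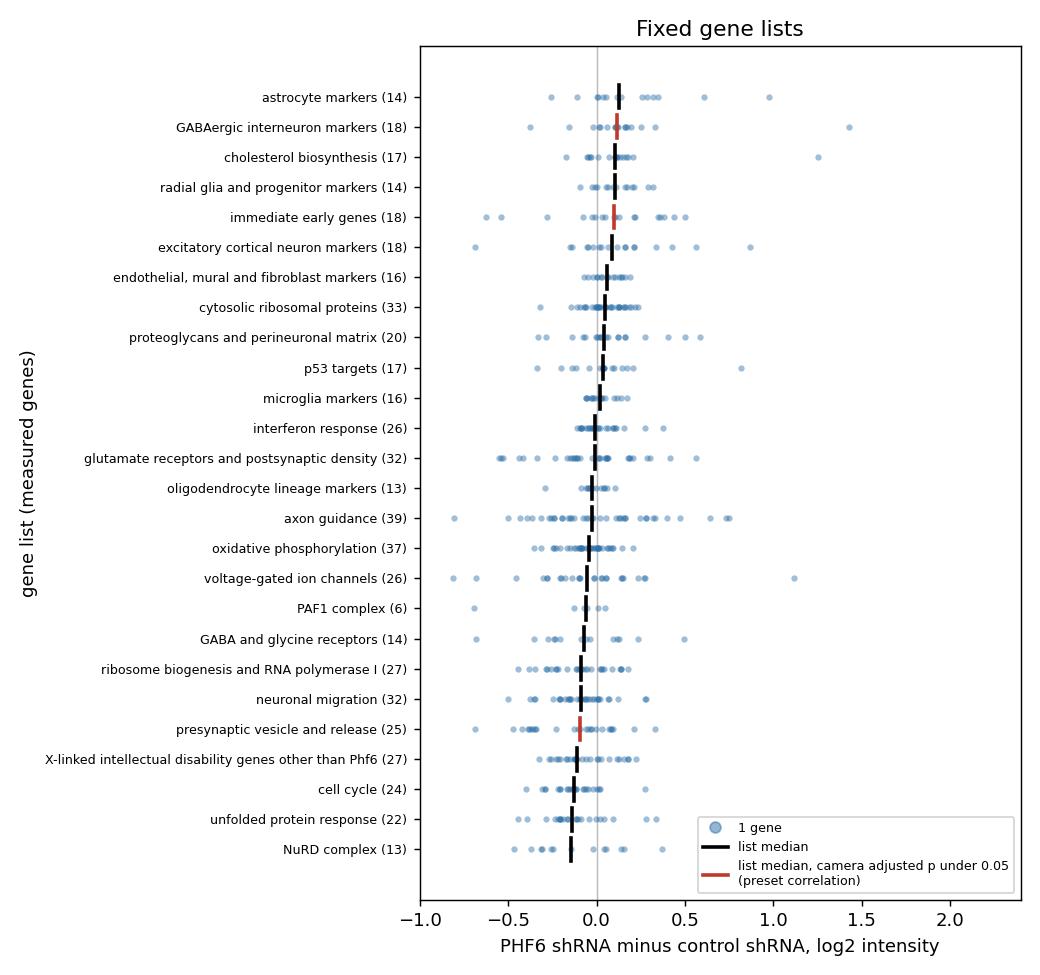
Difference between PHF6 shRNA and control shRNA arrays (log2 intensity, horizontal axis) for each measured member of the 26 fixed gene lists, with a bar at the list median; red bars mark the 3 lists that passed camera with the preset correlation. List medians lie between -0.14 and 0.13, while single genes such as Calb1 at 1.43 and Idi1 at 1.25 stand apart from their lists.

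Markers of the other cell types a cortical culture can hold did not pass as lists in the fit reported, though several did under alternatives. Excitatory neuron markers were higher in 12 of 18, with a median of 0.09 (camera adjusted p = 0.066). They passed under 5 of 15 alternatives, among them a further quantile normalization and cyclic loess, with medians of 0.14 and 0.16. Among them stood Neurod1 at 0.87 ± 0.27 and Emx1 at 0.34 ± 0.10, against the lower Slc17a6 already given. Astrocyte markers were higher in 12 of 14 with a median of 0.13 (0.055). They passed under 6 of 15 alternatives, among them the duplicate number as a block, a variance trend and the mean of probe sets. The glutamate transporter gene Slc1a2 differed by 0.98 ± 0.20 and Aldoc by 0.61 ± 0.18, while Gfap differed by 0.01 and Slc1a3 by 0.12. With an estimated correlation, 0.69 in this list, the camera adjusted p was 0.75. The astrocyte median was 0.42 without control duplicate 2 and 0.49 without PHF6 shRNA duplicate 1, against -0.07 and -0.15 without the other 2 arrays. The arrays of one group also differed in this list, with a median gap between duplicates of 0.52 in the control group and 0.63 in the PHF6 shRNA group. Such a gap enters the group difference when an array is left out. Radial glia and progenitor markers had a median of 0.10 (0.080) and gaps between duplicates of 0.31 and 0.50. Their median was 0.21 without control duplicate 2 and 0.30 without PHF6 shRNA duplicate 1, against -0.09 and -0.16 without the other 2 arrays. With the duplicate number as a block they passed toward higher signal (camera adjusted p = 0.030), but not with an estimated correlation (0.72). Cell cycle genes were lower in 20 of 24 with a median of -0.13 (0.25) and gaps of 0.43 and 0.59. The cell cycle median was 0.21 without PHF6 shRNA duplicate 1 and 0.11 without control duplicate 2. It was -0.34 without PHF6 shRNA duplicate 2 and -0.33 without control duplicate 1. With the duplicate number as a block the cell cycle list passed toward lower signal (camera adjusted p = 0.030), but not with an estimated correlation (0.79). Oligodendrocyte, microglia, and endothelial, mural and fibroblast markers had medians of -0.03, 0.02 and 0.06 and did not pass (0.76, 0.30 and 0.080), except microglia without control duplicate 1, with only 4 of 16 microglia genes above background on at least 2 arrays.

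Interferon, p53, unfolded protein and sterol responses did not pass as lists in the fit reported, and the latter pair did under alternatives. Interferon response genes had a median of -0.01 and a mean of 0.02 over 26 genes, 7 of them above background (camera adjusted p = 0.41), with no member at an unadjusted p under 0.05 and Tap1 at 0.27 ± 0.12. P53 targets had a median of 0.04 (0.32), and Tp53inp1, a stress-induced p53 target, differed by 0.82 ± 0.15 and passed adjusted over the list alone. Unfolded protein response genes were lower in 17 of 22 with a median of -0.14 (0.052), and passed under 5 of 15 alternatives, with the endoplasmic reticulum chaperone genes Dnajc3 and Pdia4 at -0.44 ± 0.09 and -0.39 ± 0.10. Cholesterol biosynthesis genes were higher in 12 of 17, with a median of 0.11 (0.052). They passed under 9 of 15 alternatives, as many as the GABAergic list, among them cyclic loess, with a median of 0.17, and over the alternatives the adjusted p ran from 0.00026 to 0.62. Apart from Idi1 none of them had an unadjusted p under 0.05.

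Lists of ribosome production and respiration did not pass in the fit reported. Ribosome biogenesis and RNA polymerase I genes were lower in 18 of 27 with a median of -0.09 (camera adjusted p = 0.075), and passed under 3 of 15 alternatives, without control duplicate 1, without PHF6 shRNA duplicate 2 and with all rows, led by Polr1e, an RNA polymerase I subunit, at -0.45 ± 0.13. Cytosolic ribosomal protein genes had a median of 0.05 (0.10), or 0.10 and 0.12 under a further quantile normalization and cyclic loess, where they passed, as they did without control duplicate 2 and without PHF6 shRNA duplicate 1. The median was below 0 without control duplicate 1 and without PHF6 shRNA duplicate 2. Oxidative phosphorylation genes had one of -0.04 (0.25), which turned to 0.03 under cyclic loess. The medians of the PAF1, axon guidance, glutamate receptor and voltage-gated channel lists also changed sign under cyclic loess.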

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

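Without a replicate block and with all 4 arrays no gene passed. The titles give both groups the same duplicate numbers, 1 and 2, and the descriptions repeat them after the letters exp, which could stand for a shared experiment. Neither says that a number marks a shared culture, litter or day. Same-numbered arrays deviated together (r = 0.57 across 17245 genes, which are not independent replicates). If the numbers mark shared experiments, the fit with the block is the appropriate one, and this stays open. A fit with the replicate block gave 909 genes past the threshold, 304 higher and 605 lower, with 3409 at an unadjusted p under 0.05, and Cspg5 passed at -0.85. It also gave 7 lists. Presynaptic and cell cycle genes passed toward lower signal. Excitatory, GABAergic, astrocyte, radial glia and cholesterol genes passed toward higher signal. Immediate early genes were not among these lists (adjusted p = 0.057), and their members Npas4 and Nr4a1 passed toward lower signal, while 4 members passed toward higher signal. With an estimated correlation none of the lists passed (camera, smallest adjusted p = 0.72), but that version could hardly pass with so few residual degrees of freedom. The fit with the block called all 24 genes named by the rule. It leaves 1 residual degree of freedom, and on simulated data with such number effects and 17245 genes it made 31.6 false calls among 231.6 on average, so its count may hold more false calls than the threshold allows. Splitting the 4 arrays by number in place of group gave 1887 genes at an unadjusted p under 0.05, as many as the real 1862, and the crossed split 68. With 3 splits no share under 0.05 is possible.

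Leaving out each array in turn gave 0 to 90 genes past the threshold and 6 to 9 lists, Phf6 between -0.10 and 0.035 and Cspg5 between -1.09 and -0.61. The lone array is then assumed to vary like the other group. The groups then also hold unequal duplicate numbers, so differences between duplicates enter the group difference. The medians of 14 lists turned sign when an array was left out: cell cycle (-0.34 to 0.21), astrocyte (-0.15 to 0.49), radial glia (-0.16 to 0.30), oligodendrocyte (-0.056 to 0.056), microglia (-0.031 to 0.063), immediate early (-0.0019 to 0.27), NuRD (-0.27 to 0.025), axon guidance (-0.10 to 0.043), glutamate receptor (-0.065 to 0.019), GABA and glycine receptor (-0.21 to 0.013), voltage-gated channel (-0.13 to 0.019), interferon (-0.022 to 0.015), ribosomal protein (-0.011 to 0.090) and proteoglycan genes (-0.077 to 0.20). So did the list members Apoe (-0.13 to 0.83), Hopx (-0.048 to 0.68), Rtf1 (-0.33 to 0.066), Esam (-0.018 to 0.35), Fcer1g (-0.0054 to 0.29) and Cnp (-0.22 to 0.052). Under cyclic loess Skic8 and Cdc73 turned to 0.0023 and 0.0079, and the medians of the PAF1, axon guidance, glutamate receptor, voltage-gated channel and oxidative phosphorylation lists to 0.0051, 0.024, 0.013, 0.0081 and 0.028. Under a further quantile normalization axon guidance and glutamate receptors turned to 0.013 and 0.010. The interferon median turned to 0.036 without the dimmest 25% of genes and to 0.064 with the background filter, where glutamate receptors turned to 0.011, and with the mean of probe sets Mbp turned to 0.0020. The number of lists past the threshold was 3 in the fit reported, 5 under a further quantile normalization and under cyclic loess, 1 after centring on the median, with array weights and with the background filter, 0 without the dimmest 25% of genes, with an estimated correlation and with fry, 6 with a variance trend, robust or not, and 7 with the mean of probe sets and with all rows. The cause was not tested. Under every alternative without the block and with all 4 arrays, 0 genes passed, including an adjusted p under 0.10 and treat. Phf6 had no value under the background filter, which removed it.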

Other observations

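The tests of cell composition, brightness and the Phf6 probe set below were chosen after the values they bear on had been seen, except the one on oligodendrocyte, microglia and vascular genes. The genes named in the next paragraph were picked for their differences between duplicates.

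Several glial and proliferation genes differed widely between the 2 arrays of one group. By at least 2-fold in both groups and in the same direction, 21 genes were higher and 2 lower in the arrays numbered 2, and 0 went opposite ways. Lcn2, a secreted siderophore-binding protein, was higher in array 2 by 2.58 log2 units in the control group and 2.77 in the PHF6 shRNA group. The radial glia gene Fabp7 was higher by 1.88 and 1.76, at log2 levels of 7.80 and 9.68 in the control arrays and 8.02 and 9.78 in the PHF6 shRNA arrays, the chemokine gene Ccl2 by 1.67 and 2.21, the oligodendrocyte-lineage gene Olig1 by 1.42 and 1.55, the astrocyte glutamate transporter gene Slc1a3 by 1.29 and 1.26, the astrocyte GABA transporter gene Slc6a11 by 1.39 and 1.24, and the mitotic gene Tpx2 by 1.24 and 1.62. Lcn2 in control duplicate 1, and Olig1 and Tpx2 in PHF6 shRNA duplicate 1, were below the background level, so these differences are not exact. The activity-regulated transcription factor gene Npas4 differed by -1.45 and -1.35.

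A hypothesis for this pattern is that the arrays numbered 2 held more dividing glial progenitor cells. Among members at least 1 log2 unit above background, cell cycle genes were higher by medians of 0.89 and 0.78 and progenitor genes by 0.73 and 0.75 in the control and PHF6 shRNA groups, so the smallest of the 4 medians was 0.73. These lists are part of the pattern itself, so the values restate it, and the hypothesis stays open. A general loss of neurons, which would raise all other cell types, stays open too. In the oligodendrocyte, microglia, and endothelial, mural and fibroblast lists, 5 genes were that bright (Col1a1, Fn1, Olig1, Olig2 and Ptprz1). Their medians were 0.25 and 0.34, with bootstrap intervals from -0.19 to 1.42 and from -0.17 to 1.55. The 5 include no microglia gene, and Olig1 was named above for its difference between duplicates, so they cannot stand for all other cell types. GABAergic markers that bright differed by -0.30 and -0.28 and excitatory markers by 0.11 and 0.02, and the design has no group for culture composition that could decide between the explanations.

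The absence of a Phf6 difference may come from a probe set that reads background, since only 1 of 4 arrays exceeded the level of 95% of olfactory and vomeronasal receptor genes. Exchanged group labels stay open, because the difference of -0.034 lies within its SE and Cspg5 was picked by the study on these samples.

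The excess of lower genes, 69.7% of those at an unadjusted p under 0.05, went with brightness: 76.1% were lower in the brightest 25% of genes and 47.3% in the second dimmest. A brightness-dependent difference between arrays is a candidate explanation, since cyclic loess, which removes such a trend, left 53.5% lower overall and 52.5% in the brightest 25%. That correction would do the same to a real fall of abundant transcripts. The brightest 25% had a median difference of -0.084 between the groups, and each PHF6 shRNA array lay below each control array, but the 2 control arrays differed by 0.092 from each other. The arrays and the shRNA therefore cannot be told apart as the source.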
